A study of Mus musculus with 24 samples.

How the data were processed

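Gene expression was measured in 24 mouse tumour samples with Clariom S arrays. Per the labels, total RNA was isolated from homogenized tumour tissue, and 250 ng of it was turned into labelled sense-strand cDNA for each array. The series concerns pancreatic ductal adenocarcinoma (PDAC), and its 4 groups of 6 samples were a control treated with vector, BMS754807 alone, hydroxychloroquine alone, and both agents together (called the combination). The labels do not say whether the 6 samples of a group came from separate animals, so each error and each p describes the spread between these samples. Doses, treatment times and the tumour site were not given in the labels used here.

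The submitters' processing notes name Transcriptome Analysis Console 4.0. The deposited table held 22206 probe sets and 24 arrays with 0 missing values, and its values were taken as log2 signal of the authors' own processing. The log base was not stated and was inferred from the values, which ran from 1.45 to 19.0 with array medians between 6.79 and 7.03. The quartiles of the arrays were nearly equal, so the values had been brought to a common scale before deposit. Background correction, normalization and summarization were not named in the sources used here. Arrays have no count depth, and the number of arrays limits the precision.

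Gene symbols came from the platform's own annotation, in which 19572 probe sets had 1 symbol, 0 had several and 2634 had none. Each gene identifier matched a current symbol in a reference table of assembly GRCm38.p6, and 0 symbols had to be updated. Where a gene had more than 1 probe set, the one with the highest mean over the 24 arrays was kept, which dropped 67 probe sets and left 19505 genes. The genome build of the array was not named, so no coordinates are given. Sample groups were copied from the titles, and no array was left out of the fit.

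One linear model with a coefficient per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, 20 residual degrees of freedom). Contrasts compared each treated group with control, the combination with each single agent, and the effect of BMS754807 in the presence and absence of hydroxychloroquine (the interaction). The 3 comparisons with control share the same 6 control tumours. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over the 19505 genes, and the threshold was an adjusted p under 0.05.

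Before the data were examined, 24 lists of pathway genes and 19 lists of cell type markers were fixed, with 800 members in all, of which 728 were measured. Of the measured genes, 12 belonged to more than 1 list. The erythroid list had 4 measured members of 9, under the minimum of 5, and the other 42 lists were tested. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 42 lists within a comparison. Chosen in advance as alternatives were camera with a correlation estimated from the data and fry, which tests whether the genes of a list move one way on balance. A list mean is the mean difference of its members, and its SE comes from the spread of the list's mean between tumours pooled over the 4 groups. A list score is the mean over members of each tumour's value minus the gene's mean over the 24 tumours. Counts called adjusted over the list alone use the Benjamini-Hochberg method within 1 list.

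Genes were named by a rule fixed in advance. As no gene passed the threshold, it named the 3 genes with the smallest p in each direction, passing over predicted, olfactory, vomeronasal and receptor segment genes. In comparisons with control it also named the members with the smallest p in each called list, and in every comparison Igf1r, Insr, Irs2, Map1lc3b, Sqstm1 and Mki67. The rule allowed up to 4 members per list, and the number was set to 3 after the called lists were seen.

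The procedure was tested on simulated data. For the gene test, values were drawn around each gene's mean with its fitted SD, and 50 genes per run were changed at each of 4 fold sizes. In 20 runs of BMS754807 against control over 19505 genes, the test recovered 31.7% of genes changed 1.5-fold, 73.8% of those changed 2-fold, 93.7% at 3-fold and 96.0% at 4-fold, with 5.23% false discoveries. Genes were drawn independently, and all 4 fold sizes were changed in the same runs. The adjusted threshold depends on how many genes change, so these shares do not hold where few do. For the list tests, whole residual arrays were dealt to the groups at random, which keeps the correlation between genes. In 50 such runs of the same comparison with no effect, camera with the preset correlation called a median of 10.5 of 42 lists and at most 20. With genes drawn independently the median was 0. An estimated correlation called a list in 0 of the 50 runs and fry in 1. When the interferon list was lowered by 0.5 log2, the preset correlation found it in 47 of 50 runs and an estimated one in 8. A missing call of the interferon list with an estimated correlation thus says little about effects of that size. Other lists were not lowered, and fry was not run on the lowered data, so their power is not known. An exact permutation of list means found the lowered interferon list in 0 runs. There 1 list alone can reach an adjusted p no lower than 0.0909, so a missing call says little about an effect of any size.

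Alternatives fixed in advance were leaving out each tumour in turn, array weights, a variance trend with robust moderation, quantile normalization repeated, centring of arrays on their medians, leaving out the dimmest 25% of genes, all probe sets, a fit to only the groups compared, and the replicate number as a block. Added after seeing the data were an exact permutation of list means per tumour over the 924 splits of 6 against 6 (two-sided, smallest possible p 0.00216), removal of the 3 arrays with a limma array weight under 0.6, and 4 sets of covariates. These were the epithelial score, the epithelial, muscle and adipocyte scores, the same with the B cell score, and the SD of each array. Contrasts of all 12 tumours given an agent against the 12 not given it were added as well. The weight limit of 0.6 was chosen after the weights were seen. For each comparison, 100 splits of the samples into groups of the same sizes were refitted, the real split included. These refits were planned after the gene counts and the simulations had been seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures.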

Results

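RNA from 24 mouse tumours was compared across 4 groups of 6: control, BMS754807, hydroxychloroquine and the combination. BMS754807 is a small molecule inhibitor of the insulin-like growth factor 1 receptor and the insulin receptor (IGF1R/IR), and hydroxychloroquine raises lysosomal pH and so blocks the last step of autophagy. By its title the series concerns blocking both in PDAC. All arrays had like medians, between 6.79 and 7.03 log2, and the number of arrays limits the precision of every value below. The SD over genes lay between 3.97 and 3.99 in the combination arrays and between 3.90 and 3.99 in the other groups. This SD is thus partly tied to the combination. A shift seen with the array SD as covariate cannot be assigned to the arrays or to the treatment there. Across genes, which are not independent replicates, the median correlation between arrays was 0.989 within groups and 0.989 between groups. In every comparison 0 of 19505 genes passed the threshold in limma, so single genes are given below as values that did not pass. Most were chosen by small p, so counts of tumours on 1 side of a mean describe them and are no further evidence.

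Marker lists of several tissues differed between tumours within groups. Skeletal muscle genes, such as Acta1, Neb and Tnni2 of the contractile apparatus, gave a list score of 3.65 in control tumour 5, 4.06 and 2.84 in BMS754807 tumours 2 and 6, 6.32 in hydroxychloroquine tumour 5 and 5.05 in combination tumour 1. The other 19 tumours lay between -2.07 and 0.55. Adipocyte markers were highest in BMS754807 tumour 6 (3.76) and hydroxychloroquine tumour 1 (2.26) and lowest in combination tumour 3 (-2.03). B and plasma cell markers stood at 2.93 in hydroxychloroquine tumour 1, 1.92 in BMS754807 tumour 5 and 1.57 in combination tumour 4, and at 0.14 or lower in the other 21. Epithelial and ductal markers, which include keratins and claudins, ran from -0.87 to 0.90, both in BMS754807 tumours. The first principal component held 18.6% of the variance, with BMS754807 tumour 6 (72.2) and control tumour 5 (51.6) at its upper end. These tumours and hydroxychloroquine tumour 4 had the lowest array weights, at 0.419, 0.518 and 0.593.

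**Figure D1:**
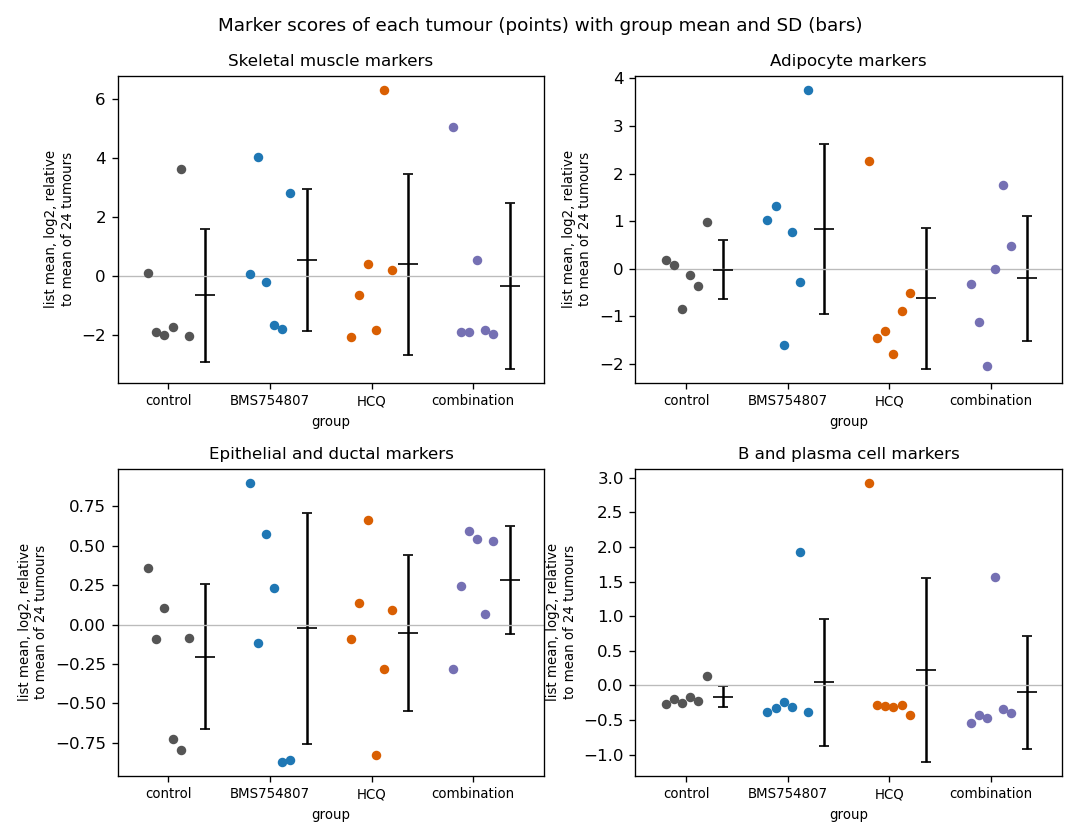
Scores of 4 marker lists (vertical axis, log2 relative to the mean of the 24 tumours) in each of the 6 tumours per group (points, horizontal axis), with the group mean and SD (bars). Muscle scores exceed 2 in 5 tumours from all 4 groups, up to 6.32, and B and plasma cell scores exceed 1 in 3 tumours, up to 2.93.

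List calls need a caution that holds for all 6 comparisons. Camera with the preset correlation called 11, 4, 13, 9, 9 and 9 of 42 lists in the order given below, while an estimated correlation and fry called 0 in each. Random regroupings of the same tumours gave medians of 10 to 12 called lists, so these calls could not be told from those of random groups. List values are therefore given with the adjusted p from an estimated correlation, as descriptions of the 24 tumours.

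BMS754807 against control asks which transcripts differed under the receptor inhibitor. Cell cycle genes stood higher in BMS754807 tumours: all 24 measured G2 and M phase genes lay above control, by a mean of 0.34 ± 0.15 log2 (SE, n = 6 per group), and 21 of 24 E2F and DNA replication genes by 0.25 ± 0.11. Among them were Prc1 (0.52 ± 0.17), which bundles microtubules in dividing cells, the spindle checkpoint kinase Bub1 (0.48 ± 0.17), the cyclins Ccne1 (0.84 ± 0.23) and Ccne2 (0.51 ± 0.15), and the ribonucleotide reductase subunit Rrm2 (0.59 ± 0.19), each above the control mean in 6 of 6 BMS754807 tumours. All 6 E2F scores with BMS754807 (0.012 to 0.22) lay above all 6 of control (-0.26 to -0.0062), with an exact permutation p of 0.00216, the smallest the splits can give, and 0.0909 after adjustment, the lowest that 1 list alone can reach over 42 lists. Of the E2F genes, 4 passed when adjusted over the list alone and 0 over all genes. Both lists were called by the preset correlation and had an adjusted p = 0.613 with an estimated correlation.

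Lists of lipid synthesis and of MYC and ribosome biogenesis also stood higher with BMS754807. All 18 cholesterol biosynthesis genes lay above control (mean 0.30 ± 0.25; adjusted p = 0.65 with an estimated correlation), as did 11 of 14 fatty acid synthesis genes (0.36 ± 0.21; 0.65), with the desaturase Scd1 at 1.11 ± 0.53 and Fasn, the fatty acid synthase, at 0.37 ± 0.22. For MYC and ribosome biogenesis 18 of 22 genes lay higher (0.16 ± 0.080; 0.65), among them Rrp12 (0.70 ± 0.21), Nolc1 (0.46 ± 0.16) and Myc (0.38 ± 0.15). Of the 16 fatty acid oxidation genes 11 lay lower (-0.069 ± 0.078; 0.613), with Acot1 at -0.75 ± 0.24 and Cpt1a at -0.26 ± 0.12, and the mean was -0.13 without BMS754807 tumour 2 and -0.023 without BMS754807 tumour 3. These lists had 0 members past the threshold over the list alone. Without BMS754807 tumour 1 the cholesterol mean was 0.17 and still called, and without BMS754807 tumour 6 the fatty acid synthesis mean was 0.26 and no longer called, as without BMS754807 tumour 4 or control tumour 5.

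Markers of other cell types differed as well. NK and cytotoxic genes lay higher in 9 of 12 (mean 0.33 ± 0.15; adjusted p = 0.613 with an estimated correlation), with the killer cell proteins perforin (Prf1, 1.32 ± 0.48) and granzyme B (Gzmb, 0.97 ± 0.45). Dendritic cell genes lay lower in 9 of 11 (-0.23 ± 0.14; 0.65), among them Xcr1 (-0.53 ± 0.22) and Batf3 (-0.53 ± 0.23) of cross-presenting dendritic cells. Fibroblast and matrix genes lay higher in 19 of 21 (0.26 ± 0.38; 0.718), adipocyte genes in 13 of 14 (0.85 ± 0.79; 0.65) and skeletal muscle genes in 16 of 16 (1.19 ± 1.53; 0.718). Without BMS754807 tumour 6 the adipocyte mean was 0.26 and the fibroblast mean 0.058, and without BMS754807 tumour 2 the muscle mean was 0.49, none of them called. Without control tumour 5 the fibroblast mean was 0.49 and the muscle mean 2.05, and without BMS754807 tumour 3 the adipocyte mean was 1.33. The fibroblast and muscle calls each ended in 6 of 12 removals: the former without control tumours 1, 2 or 3 or BMS754807 tumours 1, 5 or 6, the latter without control tumours 2, 3, 4 or 6 or BMS754807 tumours 2 or 6. The NK call ended without control tumours 1 or 3 or BMS754807 tumour 6, and the dendritic and fatty acid oxidation calls in 5 of 12 removals of 1 tumour each, with a dendritic mean of -0.15 without control tumour 6.

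No single gene passed: 0 of 19505 genes in limma, with 1146 at an unadjusted p under 0.05 (543 higher, 603 lower) where chance gives 975 on average. How widely such counts vary between random groupings was not tested, here or in the comparisons below. The smallest adjusted p was 0.235, for Zfp280b (probe set TC1000000733.mm.2), a zinc finger gene at 8.88 ± 0.20 (SD, n = 6) with BMS754807 and 8.14 ± 0.30 in control. Next among genes that lay higher were the serotonin receptor gene Htr1b (0.82 ± 0.18 log2, SE) and Ccdc86 (0.84 ± 0.19). Lower were Lbp (probe set TC0200002426.mm.2; -1.08 ± 0.24), which encodes the lipopolysaccharide-binding protein, the chromatin remodeller Smarca1 (-0.98 ± 0.23) and Ptrhd1 (-0.61 ± 0.14), all with an adjusted p of 0.793. Only Htr1b passed in any of the alternative fits, at 1.01 ± 0.15 without BMS754807 tumour 1. The transcripts of the targets gave small differences: Igf1r -0.018 ± 0.16 and Insr -0.027 ± 0.12. The substrate gene Irs2 lay lower, at -0.32 ± 0.28, with a wide SE. Receptor activity was not measured on these arrays. The IGF and insulin receptor list stood at -0.0045 ± 0.11 and FOXO targets, which are transcribed when insulin signalling is low, at -0.060 ± 0.11, neither called. Mki67, a marker of cycling cells, lay at 0.32 ± 0.16, and the autophagy genes Map1lc3b and Sqstm1 at -0.097 ± 0.12 and -0.037 ± 0.17.

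Hydroxychloroquine against control asks what the autophagy inhibitor did alone. Interferon-stimulated genes stood lower: all 26 measured members lay below control, by a mean of -0.55 ± 0.22 log2 (SE, n = 6 per group). The largest differences among the named members were those of the antiviral genes Ifit3 (-1.11 ± 0.44), Oasl1 (-1.06 ± 0.27) and Irf7 (-1.02 ± 0.36), each below the control mean in 6 of 6 hydroxychloroquine tumours. The exact permutation p of the list was 0.0173 and 0.727 after adjustment over the lists, and the adjusted p = 0.701 with an estimated correlation. Of its genes 1 passed when adjusted over the list alone and 0 over all genes. The mean ranged from -0.64 to -0.48 when 1 tumour was left out, with the preset call held each time.

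Immediate-early genes, also raised by tissue handling, lay higher in 13 of 15 with hydroxychloroquine (mean 0.28 ± 0.16; adjusted p = 0.875 with an estimated correlation), with Egr1 at 0.61 ± 0.18 and Nr4a1 at 0.60 ± 0.18, the only 2 that passed over the list alone. Fibroblast and matrix genes lay higher in 19 of 21 (0.35 ± 0.38; 0.875), among them the proteoglycan gene Lum (1.15 ± 0.48), Col5a1 (0.82 ± 0.44) and Mmp2 (0.82 ± 0.50). Without hydroxychloroquine tumour 4 the fibroblast mean was 0.11 and not called, nor was it without control tumour 2, and without control tumour 5 it was 0.59. NK and cytotoxic genes lay higher in 11 of 12 (0.32 ± 0.15; 0.701), with Prf1 at 0.98 ± 0.48 and Klrk1 at 0.33 ± 0.19, and the call ended in 4 of the 12 removals of 1 tumour. Without hydroxychloroquine tumour 1, which held the most B cell and T cell transcripts, 12 lists were called instead of 4, and there were 10 without control tumour 6, 8 without hydroxychloroquine tumour 4, and 7 without control tumour 5 or hydroxychloroquine tumour 6.

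Of the 19505 genes 0 passed in limma, and 939 had an unadjusted p under 0.05 (474 higher, 465 lower) against 975 by chance. The smallest adjusted p, 0.239, belonged to the kinase gene Stk26 (probe set TC0X00000454.mm.2), at 8.40 ± 0.34 (SD, n = 6) with hydroxychloroquine and 7.20 ± 0.24 in control. Of the alternative fits it passed only with the replicate number as block (1.21 ± 0.18 log2, SE), although the numbers do not pair the tumours. Angpt1, which encodes a ligand of the endothelial receptor Tek, lay higher by 1.11 ± 0.24 log2 (SE) and Cth, an enzyme of cysteine synthesis, by 0.85 ± 0.19. Lower were the meiosis gene Msh4 (probe set TC0300003169.mm.2; -0.69 ± 0.16), Bend7 (-0.63 ± 0.15) and the defensin gene Defb6 (-0.88 ± 0.21). Transcripts of the compartment that the agent acts on differed little: the lysosome list stood at -0.0084 ± 0.063 and the autophagy list at -0.0054 ± 0.055, with Map1lc3b at -0.14 ± 0.12 and Sqstm1 at 0.068 ± 0.17. Lysosomal pH and autophagy itself were not measured on these arrays. Igf1r lay at -0.062 ± 0.16, Insr at 0.075 ± 0.12, Irs2 at 0.40 ± 0.28 and Mki67 at -0.098 ± 0.16.

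**Figure D2:**
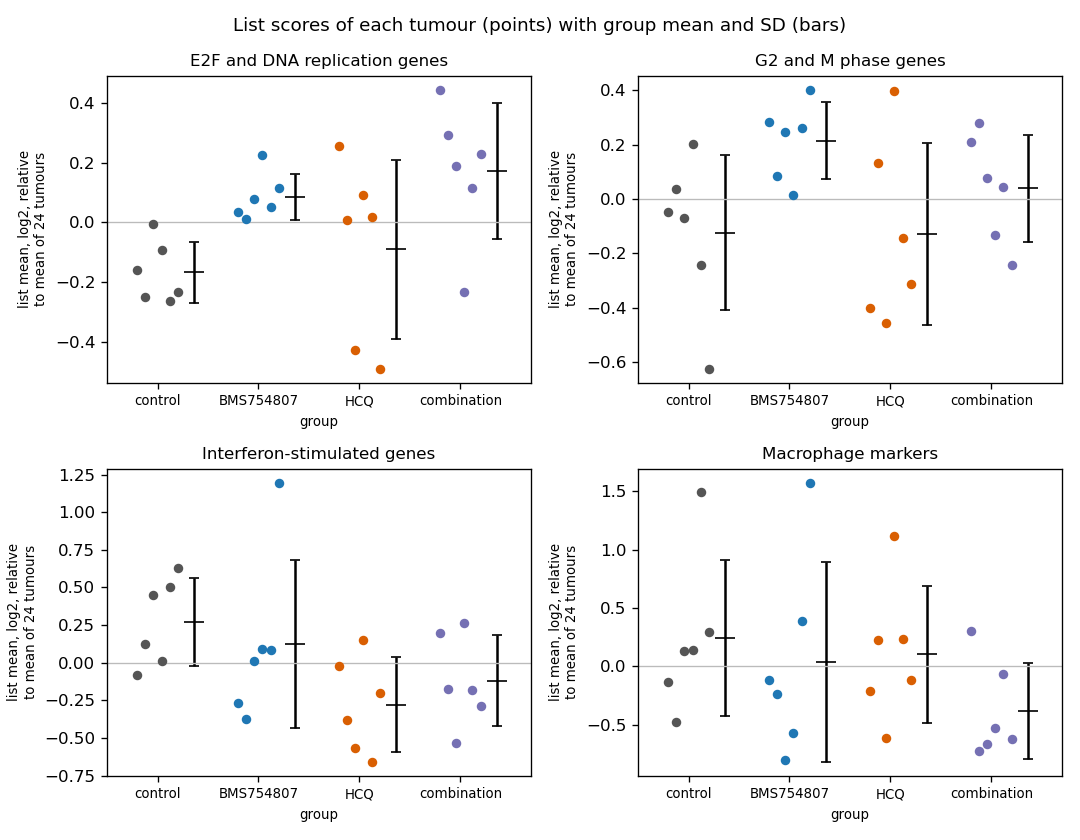
Scores of 4 gene lists (vertical axis, log2 relative to the mean of the 24 tumours) in each of the 6 tumours per group (points, horizontal axis), with the group mean and SD (bars). All 6 E2F scores with BMS754807 (0.012 to 0.22) lie above those of control (-0.26 to -0.0062), while the combination ranges from -0.23 to 0.44; interferon scores average 0.27 in control and -0.28 with hydroxychloroquine.

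The combination against control asks what both agents did together. Replication genes stood higher and markers of macrophages, dendritic cells and interferon response lower. Of 24 E2F and DNA replication genes 22 lay higher, by a mean of 0.34 ± 0.11 log2 (SE, n = 6 per group), with DNA polymerase alpha (Pola1, 0.65 ± 0.15), Rfc4 (0.47 ± 0.13) and Pcna (0.32 ± 0.094), both of the replication clamp machinery, above the control mean in 6 of 6 combination tumours. Adjusted over the list alone 6 of them passed and over all genes 0, and the adjusted p = 0.27 with an estimated correlation. G2 and M phase genes lay higher in 20 of 24 (0.16 ± 0.15; adjusted p = 0.776 with an estimated correlation), with the mitotic kinesin Kif11 at 0.32 ± 0.16. Without control tumour 6 that mean was 0.064 and no longer called.

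All 15 macrophage genes lay lower in the combination (mean -0.63 ± 0.38; adjusted p = 0.776 with an estimated correlation), among them the scavenger receptor Cd163 (-1.27 ± 0.54), the chemokine receptor Cx3cr1 (-0.84 ± 0.26) and the mannose receptor Mrc1 (-0.65 ± 0.29). Without control tumour 5 the macrophage mean was -0.38 and still called. All 11 dendritic cell genes lay lower (-0.36 ± 0.14; 0.27), with Cd209a at -0.81 ± 0.34 and Batf3 at -0.58 ± 0.23. Interferon-stimulated genes lay lower in 23 of 26 (-0.39 ± 0.22; 0.776), with Ifit3 at -1.12 ± 0.44 and the ubiquitin-like Isg15 at -0.85 ± 0.36. Antigen presentation genes lay lower in 13 of 15 (-0.37 ± 0.36; 0.776), with the class II genes H2-Eb1 (-1.01 ± 0.47) and H2-Aa (-0.97 ± 0.49), a call lost in 4 of 12 removals of 1 tumour, with a mean of -0.16 without control tumour 6. Of these lists 0 members passed over the list alone.

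Epithelial and ductal markers stood higher in 16 of 18 (mean 0.49 ± 0.30; adjusted p = 0.776 with an estimated correlation), among them the tight junction gene Cldn3 (1.22 ± 0.50), the membrane protease St14 (1.57 ± 0.74) and the ductal transcription factor Sox9 (0.23 ± 0.12), a call lost without control tumour 4. Endothelial genes lay lower in 16 of 17 (-0.36 ± 0.34; 0.776), with Cldn5 at -0.63 ± 0.36, and pericyte genes in 7 of 9 (-0.26 ± 0.35; 0.776), with Notch3 at -0.76 ± 0.28. Without control tumour 5 the endothelial mean was -0.11 and the pericyte mean 0.035, neither called. The pericyte call also ended without combination tumours 2 or 6. With the epithelial score as covariate, added after seeing the data, the endothelial mean was 0.029, the pericyte mean 0.099, and 7 lists were called instead of 13. With the SD of each array as covariate those means were 0.15 and 0.17, and 10 lists were called, which held only 5 of the 13.

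Sterol and secretory pathway genes completed the called lists of the combination. All 18 cholesterol biosynthesis genes lay higher (mean 0.30 ± 0.25; adjusted p = 0.776 with an estimated correlation), with Dhcr7 at 0.51 ± 0.25 and Cyp51 at 0.57 ± 0.31, and with the SD of each array as covariate the mean was -0.0024. All 14 fatty acid synthesis genes lay higher (0.18 ± 0.21; 0.776), with Elovl5 at 0.30 ± 0.12, and without combination tumour 5 the mean was 0.095 and not called, nor was it without control tumour 5 or combination tumour 1. Unfolded protein response genes of the endoplasmic reticulum lay higher in 16 of 17 (0.15 ± 0.077; 0.776), where Sdf2l1 (0.70 ± 0.20) alone passed over the list alone. Immediate-early genes lay higher in 13 of 15 (0.17 ± 0.16; 0.776), with Egr1 at 0.42 ± 0.18, and without combination tumour 2 the mean was 0.072, 1 of 6 removals of 12 that ended the call.

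For single genes 0 of 19505 passed in limma, with 986 at an unadjusted p under 0.05 (519 higher, 467 lower) against 975 by chance and a smallest adjusted p of 0.849. The genes of smallest p that lay higher were the kinetochore gene Cenph (probe set TC1300002542.mm.2), at 7.87 ± 0.32 (SD, n = 6) and 6.96 ± 0.48 in control, Pola1 given above, and the smooth muscle gene Cnn1 (1.39 ± 0.34 log2, SE). Lower were Mical2 (probe set TC0700001644.mm.2; -0.53 ± 0.11), an enzyme that oxidizes actin, Pheta2 (-1.12 ± 0.25) and Kirrel2 (-0.60 ± 0.15). Igf1r lay at 0.052 ± 0.16, Insr at 0.098 ± 0.12, Irs2 at 0.20 ± 0.28, Map1lc3b at -0.083 ± 0.12, Sqstm1 at -0.013 ± 0.17 and Mki67 at 0.12 ± 0.16. The IGF and insulin receptor list (-0.018 ± 0.11), FOXO targets (0.073 ± 0.11), lysosome (-0.068 ± 0.063) and autophagy (0.042 ± 0.055) were not called.

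**Figure D3:**
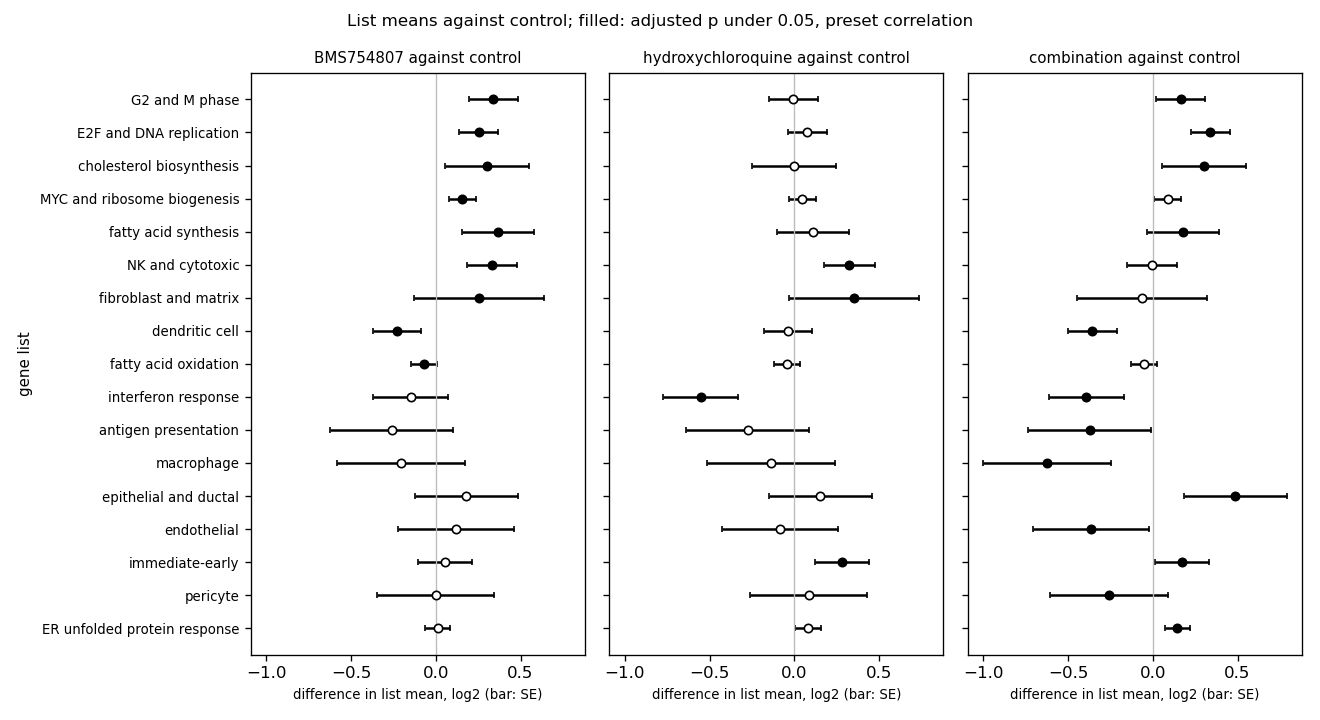
Difference in list mean from control (horizontal axis, log2, bars SE) for the 17 lists called in at least 1 comparison with control apart from muscle and adipocyte markers, which lie off this scale; filled points have an adjusted p under 0.05 with the preset correlation, and an estimated correlation called 0. E2F genes lie at 0.25 with BMS754807 and 0.34 in the combination, and interferon-stimulated genes at -0.55 with hydroxychloroquine and -0.39 in the combination.

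The combination against BMS754807 asks what hydroxychloroquine added to the receptor inhibitor. Vessel, fat and macrophage markers stood lower: all 17 endothelial genes by a mean of -0.48 ± 0.34 log2 (SE, n = 6 per group), 13 of 14 adipocyte genes by -1.03 ± 0.79, all 15 macrophage genes by -0.42 ± 0.38, 19 of 21 fibroblast genes by -0.32 ± 0.38 and 20 of 26 interferon-stimulated genes by -0.24 ± 0.22. Cell cycle genes of G2 and M phase lay lower in 20 of 24 (-0.18 ± 0.15). Autophagy genes lay higher in 23 of 31 (0.12 ± 0.055), with an exact permutation p of 0.00649 and 0.273 after adjustment, FOXO targets in 17 of 23 (0.13 ± 0.11) and unfolded protein response genes in 12 of 17 (0.14 ± 0.077). All 9 had an adjusted p = 0.813 with an estimated correlation. Without BMS754807 tumour 6, high in muscle and fat markers, 0 lists were called, the endothelial mean was -0.23, the adipocyte mean -0.45, the macrophage mean -0.11, the fibroblast mean -0.12 and the interferon mean -0.030. The fibroblast mean was -0.48 without BMS754807 tumour 4 and 0.10 with the SD of each array as covariate. Without combination tumour 3 there were 2 called lists, without combination tumour 2 there were 4 and without BMS754807 tumour 4 there were 14. The fibroblast call ended in 6 of 12 removals of 1 tumour, the autophagy, FOXO and interferon calls in 4 each, the macrophage call in 3, the adipocyte and unfolded protein response calls in 2 each, and the endothelial and G2 and M phase calls in 1 each. With the 4 covariate sets, added after seeing the data, 3 to 5 lists were called instead of 9.

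In limma 0 of 19505 genes passed, and 1679 had an unadjusted p under 0.05 (1001 higher, 678 lower) against 975 by chance on average. The spread of this count between random groupings was not tested, so it is not read as an excess. Timp3 (probe set TC1000001044.mm.2), an inhibitor of matrix metalloproteinases, stood at 12.2 ± 0.15 (SD, n = 6) in the combination and 11.6 ± 0.21 with BMS754807. Lbp lay higher by 1.19 ± 0.24 log2 (SE) and Tifa, an adaptor of NF-kB signalling, by 1.40 ± 0.28. Lower were Gemin7 (probe set TC0700002488.mm.2; -0.69 ± 0.13), which serves in the assembly of spliceosomal particles, Atp6v0d2 (-1.49 ± 0.31), a subunit of the proton pump of lysosomes, and the cartilage proteoglycan Acan (-1.34 ± 0.29). The first 5 of these had an adjusted p of 0.179 and Acan 0.221, each with 6 of 6 combination tumours on the same side of the BMS754807 mean. The low Lbp of BMS754807 tumours enters both this comparison and the one with control. Genes that passed only in an alternative fit were Gemin7 (-0.79 ± 0.12) without combination tumour 6 and Htr1b (-0.93 ± 0.15) without BMS754807 tumour 1. With epithelial, muscle and adipocyte scores as covariates, added after seeing the data, the hyaluronidase gene Hyal5 (-1.26 ± 0.18) and the hyaluronan synthase gene Has3 (-1.16 ± 0.19) passed. With the B cell score added only Hyal5 did (-1.26 ± 0.19), and with the epithelial score or the array SD alone 0 genes passed, so both depend on the set of covariates. Igf1r lay at 0.070 ± 0.16, Insr at 0.12 ± 0.12, Irs2 at 0.52 ± 0.28, Map1lc3b at 0.013 ± 0.12, Sqstm1 at 0.023 ± 0.17 and Mki67 at -0.20 ± 0.16.

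The combination against hydroxychloroquine asks what the receptor inhibitor added to the autophagy inhibitor. Replication genes stood higher again, 23 of 24 E2F genes by a mean of 0.26 ± 0.11 log2 (SE, n = 6 per group), where 3 passed over the list alone and 0 over all genes (adjusted p = 0.562 with an estimated correlation; exact permutation p 0.128). G2 and M phase genes lay higher in 23 of 24 (0.17 ± 0.15), cholesterol biosynthesis genes in 18 of 18 (0.30 ± 0.25) and epithelial genes in 15 of 18 (0.33 ± 0.30), each with an adjusted p = 0.78 with an estimated correlation. Macrophage genes lay lower in 15 of 15 (-0.49 ± 0.38; 0.78), fibroblast genes in 20 of 21 (-0.42 ± 0.38; 0.78), dendritic cell genes in 10 of 11 (-0.32 ± 0.14; 0.562), NK and cytotoxic genes in 11 of 12 (-0.33 ± 0.15; 0.562) and T cell genes in 11 of 12 (-0.36 ± 0.35; 0.78). Hydroxychloroquine tumour 1 carried the T cell difference, which was 0.061 without it, while 20 lists were then called instead of 9, with a cholesterol mean of 0.47 and a fibroblast mean of -0.65. Without hydroxychloroquine tumour 4 the fibroblast mean was -0.18 and the epithelial mean 0.18, neither called, and the macrophage mean -0.28 and the G2 and M phase mean 0.28, both still called. The fibroblast call also ended without combination tumour 2, and the T cell call without combination tumours 1 or 3. Without hydroxychloroquine tumour 6 the cholesterol mean was 0.17 and not called, and without hydroxychloroquine tumour 3 the G2 and M phase mean was 0.10 and still called. With the SD of each array as covariate 4 means changed sign: macrophage (0.041), cholesterol (-0.060), epithelial (-0.13) and fibroblast (0.18).

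Here too 0 of 19505 genes passed in limma, with 1052 at an unadjusted p under 0.05 (546 higher, 506 lower) against 975 by chance and a smallest adjusted p of 0.769. Spidr (probe set TC1600001256.mm.2) stood at 10.03 ± 0.16 (SD, n = 6) in the combination and 9.51 ± 0.14 with hydroxychloroquine, and Mms22l lay higher by 0.64 ± 0.14 log2 (SE). Both genes act in homologous recombination. Bco1, which cleaves carotenoids, lay higher by 0.91 ± 0.21. Lower were Rln3 (probe set TC0800002566.mm.2; -0.58 ± 0.13), Mzf1 (-0.57 ± 0.14) and Evc (-0.68 ± 0.17), a gene of the primary cilium. Igf1r lay at 0.11 ± 0.16, Insr at 0.023 ± 0.12, Irs2 at -0.20 ± 0.28, Map1lc3b at 0.055 ± 0.12, Sqstm1 at -0.082 ± 0.17 and Mki67 at 0.22 ± 0.16.

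The interaction asks whether the effect of BMS754807 differed with hydroxychloroquine present. Stromal and cytotoxic markers lay below the sum of the single effects: 19 of 21 fibroblast genes by a mean of -0.67 ± 0.54 log2 (SE, 6 tumours in each of 4 groups), 11 of 12 NK and cytotoxic genes by -0.66 ± 0.21, 17 of 17 endothelial genes by -0.40 ± 0.48, 14 of 18 TGF-beta and epithelial-mesenchymal transition genes by -0.26 ± 0.20, 20 of 24 G2 and M phase genes by -0.17 ± 0.21 and 16 of 16 muscle genes by -1.93 ± 2.17. Above the sum lay 24 of 26 interferon-stimulated genes (0.31 ± 0.31), 16 of 17 hypoxia genes (0.31 ± 0.26) and 13 of 17 glycolysis genes (0.18 ± 0.13). The NK list had an adjusted p = 0.235 with an estimated correlation and the other 8 had 0.848. The preset calls of the fibroblast and NK lists held in all 24 removals of 1 tumour, in which the fibroblast mean ran from -0.91 to -0.43 and the NK mean from -0.74 to -0.57, while with the SD of each array as covariate the fibroblast mean was -0.15 and the endothelial mean 0.15, neither called. The other calls ended in 16 of the 24 removals for glycolysis, 13 for TGF-beta, 12 for endothelial, 10 for G2 and M phase, 7 for interferon, 6 for hypoxia and 3 for muscle genes. Without BMS754807 tumour 6 the endothelial mean was -0.15 and the interferon mean 0.52, and without control tumour 5 the endothelial mean was -0.66. Without hydroxychloroquine tumour 4 the G2 and M phase mean was -0.064, the TGF-beta mean -0.17 and the fibroblast mean -0.43. Without hydroxychloroquine tumour 5, the tumour with the most muscle transcripts, the muscle mean was -0.74 and 2 lists were called instead of 9, and without combination tumour 1 the muscle mean was -3.0. Without BMS754807 tumours 2 or 5 there were 4 lists, and 5 without control tumour 2, BMS754807 tumour 6, hydroxychloroquine tumour 2 or combination tumour 2.

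Of 19505 genes 0 passed in limma, and 985 had an unadjusted p under 0.05 (534 higher, 451 lower) against 975 by chance, with a smallest adjusted p of 0.817. Defb6 (probe set TC0800000182.mm.2; 1.29 ± 0.30 log2, SE), the inflammatory caspase gene Casp4 (1.00 ± 0.24) and Zfp939 (1.16 ± 0.29) lay above the sum of the single effects. Below it lay Mzf1 (probe set TC0700002361.mm.2; -0.92 ± 0.20), Cables1 (-1.28 ± 0.28) and Atf7ip2 (-1.11 ± 0.24). With the epithelial, muscle and adipocyte scores as covariates Hyal5 passed (-1.62 ± 0.25), and with the other 3 covariate sets 0 genes did. Igf1r lay at 0.13 ± 0.23, Insr at 0.050 ± 0.17, Irs2 at 0.12 ± 0.40, Map1lc3b at 0.15 ± 0.17, Sqstm1 at -0.045 ± 0.24 and Mki67 at -0.10 ± 0.22.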

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

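The tests in this part were chosen after the results were seen, apart from the test of immune cell content, the interaction and Dixon's test for a single tumour far from the other 5 of its group. Dixon's test was applied to 548 groups of 6 values and found 39, where chance gives about 1 in 20. Hydroxychloroquine tumour 1 held 10 of the 39, control tumour 5 held 6 and combination tumour 1 held 4, and the values of 1 tumour are not independent of each other. Flagged values marked low lay below the other 5 of their group, and the rest lay above.

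Control tumour 5 lay apart in the scores of skeletal muscle (3.65) and pericyte markers (1.51) and in Tnni2 (11.09), the endothelial genes Cldn5 (8.84) and Sox18 (8.42), and Mms22l (9.20 log2, low). Ptrhd1 lay apart in control tumour 3 (4.98, low), Plin1, which coats lipid droplets, in control tumour 6 (6.45) and Cth in control tumour 2 (4.78, low). Among BMS754807 tumours, number 6 lay apart in the interferon score (1.19) and in the lipase gene Lipe (11.96), number 5 in the T cell score (0.79), number 4 in Kif11 (12.66, low) and Cables1 (6.33), and number 2 in the desaturase gene Fads1 (11.96, low).

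Hydroxychloroquine tumour 1 lay apart in the scores of MYC and ribosome biogenesis (0.37), fatty acid synthesis (1.19), adipocytes (2.26), the unfolded protein response (0.35), autophagy (-0.26, low) and T cells (2.28), and in Rrp12 (10.07), Scd1 (15.84), Thrsp (9.78) and Plin1 (8.17). Number 5 lay apart in the muscle score (6.32), Tnni2 (13.79) and Smarca1 (5.46, low), and number 4 in Cldn5 (8.71). Among combination tumours, number 1 lay apart in the muscle score (5.05), Tnni2 (12.01), Zfp280b (9.04) and the immediate-early gene Jun (12.52, low). Number 2 did so in Ccdc86 (8.66, low), Lum (9.50, low) and Tek (5.01, low), number 5 in Scd1 (15.36), number 3 in Cth (5.36, low) and number 4 in Gzmk (3.35).

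The effect of BMS754807 differed with and without hydroxychloroquine, by camera with the preset correlation, in 9 lists: G2 and M phase (-0.17), glycolysis (0.18), hypoxia (0.31), interferon response (0.31), TGF-beta and epithelial-mesenchymal transition (-0.26), fibroblast (-0.67), endothelial (-0.40), NK (-0.66) and muscle (-1.93). With an estimated correlation the difference passed in 0 of them. In 62 of 100 splits of the 24 tumours at least 9 lists were called, with 18 the highest of the other splits, so chance could not be excluded.

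Skeletal muscle transcripts stood high in 5 tumours from all 4 groups. The 16 muscle genes followed each other over the 24 tumours, with a median pairwise r of 0.917, and Acta1 reached 16.36 in hydroxychloroquine tumour 5 and 14.02 in control tumour 5 against 4.33 in control tumour 3. After quantile normalization 0.998 of the gap between the highest and lowest score was left. The arrays already had nearly equal quartiles, so that step could change little and decides nothing. The array medians ran only from 6.79 to 7.03, while muscle scores ran from -2.07 to 6.32. This argues against a scale difference left between the deposited arrays. The score of 3.65 in a control tumour argues against treatment as the whole cause. Muscle tissue taken along with some tumours is a candidate explanation that these values leave open. How many of the 16 genes the tumour cells also express was not tested.

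Interferon-stimulated genes stood lower with hydroxychloroquine, by -0.55 ± 0.22 log2. With the scores of macrophages, T cells, B and plasma cells and dendritic cells as covariates the difference was -0.55 ± 0.18, which argues against the content of these cells as the whole cause. Chance among the lists stays open: the exact permutation p was 0.727 after adjustment, but 1 list alone could reach no lower than 0.0909, so that test could not exclude chance. Whether hydroxychloroquine acts likewise beside BMS754807 also stays open, because the exact p of the combination against BMS754807 was 0.426 and that difference rested on BMS754807 tumour 6 (-0.030 without it). That hydroxychloroquine may lower the interferon response is thus a hypothesis, found and tested on the same data.

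E2F and DNA replication genes stood higher with BMS754807, by 0.25 ± 0.11 log2. With the epithelial score as covariate the difference was 0.27 ± 0.11 and with the SD of each array 0.25 ± 0.12, which argues against the share of epithelial cells and the spread of the arrays as whole causes. Chance among the lists stays open: the exact permutation p of 0.0909 after adjustment is the lowest that 1 list alone can reach, so that test could not exclude chance. Beside hydroxychloroquine the exact p was 0.128, so whether BMS754807 acts likewise there cannot be told. That BMS754807 may raise replication transcripts is thus a hypothesis, found and tested on the same data.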

How the results depend on the processing

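Added after seeing the data were the exact permutation, the removal of the 3 tumours of low weight and the 4 covariate sets; the other alternatives below were planned. Apart from leaving out single tumours, 1960 values of named genes and 303 of lists kept their direction and side of the threshold. As no gene passed in the main fit, no named gene could lose a call. Most named genes were chosen by small p, which makes a change of direction unlikely, so their tally says little about stability. Of the counts, 223 of genes and 37 of lists stayed within 1.5 times the reported one. A like count of lists need not hold the same lists. In the interaction 9 lists were called with the array SD as covariate, but only 3 of the reported 9 were among them. With the replicate number as block all 9 were. For BMS754807 against control without the 3 tumours of low weight 13 lists were called, with 7 of the reported 11. Every reported gene count was 0, so the 223 stayed at 0, and a gene count could only rise. Higher were 8 counts of genes, those by direction included, while 27 counts of lists were lower and 1 higher by more than 1.5 times. Calls were lost with the direction kept for 264 list values in these alternatives and for 153 when 1 tumour was left out. In direction 31 values of named genes and 15 of lists reversed, and 47 and 2 when 1 tumour was left out. Each list value that reversed lost its call as well and is not in the counts of lost calls above. For each value below the cause was not tested unless stated.

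Camera with an estimated correlation and fry called 0 lists in each of the 6 comparisons, and the exact permutation 0 in each of the 5 it was run for. The latter says little, since 1 list alone could reach an adjusted p no lower than 0.0909. The list means are the same in all of these tests, which differ in their treatment of correlation between genes and, for fry and the permutation, in testing against no change instead of against other genes. Signal over background was not given with the deposited values, and leaving out the dimmest genes ended 5 list calls.

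Without control tumour 5, BMS754807 tumour 6 and hydroxychloroquine tumour 4, Sqstm1 was 0.036 with BMS754807 and 0.059 in the combination against control, and the pericyte mean was 0.035 in the combination. The combination against BMS754807 then had 0 lists. Against hydroxychloroquine Insr was -0.018 and Sqstm1 0.015, and the interaction of Insr was -0.010.

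With epithelial, muscle and adipocyte scores as covariates, Insr was 0.0075 and Sqstm1 0.037 with BMS754807, and Sqstm1 -0.018 with hydroxychloroquine, where 9 lists were called. In the combination Igf1r was -0.040 and the endothelial mean 0.0046. Against BMS754807 there were 2 genes and 3 lists, Igf1r was -0.0054 and Sqstm1 -0.049, and against hydroxychloroquine Sqstm1 was 0.0060. The interaction had 1 gene and 4 lists, and Irs2 was -0.054.

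With the B cell score added, Insr was 0.022 and Sqstm1 0.052 with BMS754807. In the combination 6 lists were called, Igf1r was -0.029, Sqstm1 0.0061, the endothelial mean 0.017 and the pericyte mean 0.0062. Against BMS754807 there were 1 gene and 3 lists, Igf1r was -0.0036 and Sqstm1 -0.046. The interaction of Irs2 was -0.21.

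The SD of each array was partly tied to the combination, so shifts in its contrasts cannot be assigned to the arrays or to the treatment. With this SD as covariate Igf1r was 0.0019 with BMS754807. In the combination Tek was 0.019, Sqstm1 0.18, and the means of cholesterol, endothelial and pericyte genes -0.0024, 0.15 and 0.17. Against BMS754807 there were 5 lists and a fibroblast mean of 0.10. Against hydroxychloroquine Sqstm1 was 0.16, and the cholesterol, epithelial, fibroblast and macrophage means were -0.060, -0.13, 0.18 and 0.041. In the interaction Sqstm1 was 0.16 and the endothelial mean 0.15.

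With the epithelial score alone the combination had 7 lists, Igf1r -0.0093, Sqstm1 0.0047, an endothelial mean of 0.029 and a pericyte mean of 0.099. There were 4 lists against BMS754807, 5 against hydroxychloroquine and 5 for the interaction. With the replicate number as block 1 gene passed with hydroxychloroquine, Stk26, although the numbers do not pair the tumours. After centring on medians Map1lc3b was -0.025 and Sqstm1 -0.015 in the combination against BMS754807. Insr against hydroxychloroquine was -0.031 with array weights and -0.017 after quantile normalization. No scaling moved the median of all genes by more than 0.0633.

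When 1 tumour was left out, BMS754807 against control had 0 to 1 genes, Igf1r ran from -0.10 to 0.057 (highest without BMS754807 tumour 4), Insr from -0.071 to 0.016 (BMS754807 tumour 3) and Sqstm1 from -0.13 to 0.038 (BMS754807 tumour 4). With hydroxychloroquine 4 to 12 lists were called, Igf1r ran from -0.14 to 0.055 (highest without hydroxychloroquine tumour 1) and Sqstm1 from -0.028 (without number 4) to 0.21. In the combination Igf1r ran from -0.023 (without combination tumour 3) to 0.11, Sqstm1 from -0.11 to 0.059 (without control tumour 5), Mki67 from -0.015 (without control tumour 6) to 0.20 and the pericyte mean from -0.37 to 0.035 (without control tumour 5).

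Against BMS754807 the combination had 0 to 1 genes and 0 to 14 lists, with 0 without BMS754807 tumour 6. Igf1r ran from -0.0057 to 0.15, Map1lc3b from -0.027 to 0.057 and Sqstm1 from -0.051 to 0.072, lowest without BMS754807 tumours 4, 3 and 4. Against hydroxychloroquine it had 8 to 20 lists, with 20 without hydroxychloroquine tumour 1. Igf1r ran from -0.0037 to 0.19, Insr from -0.072 to 0.088, Map1lc3b from -0.035 to 0.12, Sqstm1 from -0.23 to 0.015 and the T cell mean from -0.52 to 0.061. Without hydroxychloroquine tumour 1 the first 3 were lowest and the T cell mean highest, and Sqstm1 was highest without number 4. The interaction had 2 to 13 lists, with 2 without hydroxychloroquine tumour 5 and 13 without combination tumour 5. There Insr ran from -0.045 to 0.11, Irs2 from -0.044 to 0.32, Mki67 from -0.19 to 0.033 and Sqstm1 from -0.19 to 0.052. Insr and Irs2 were lowest without hydroxychloroquine tumour 1, Mki67 highest without control tumour 6 and Sqstm1 highest without hydroxychloroquine tumour 4.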

Other observations

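All tests in this part were chosen after the results were seen, and the genes named here after their values were seen. Scores of further cell types varied between tumours. Keratinocyte markers reached 1.17 in combination tumour 4 and lay between -0.34 and 0.25 in the other 23. Hepatocyte markers reached 0.75 in the same tumour, from a lowest score of -0.39. Their highest scores in the other groups were 0.48 with hydroxychloroquine, 0.27 in control and 0.20 with BMS754807. Acinar markers, from the enzyme-secreting cells of the pancreas, ran only from -0.16 to 0.18, islet markers from -0.25 to 0.26 and Schwann cell markers from -0.37 to 0.35. Neutrophil markers were highest in control tumour 5 (1.41) and BMS754807 tumour 6 (1.07), the tumours that also had the highest macrophage scores (1.49 and 1.57).

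Averaged over hydroxychloroquine, the 12 tumours given BMS754807 were compared with the 12 not given it. In limma 0 genes passed (smallest adjusted p 0.574, 1115 at an unadjusted p under 0.05). The F-box gene Fbxo48 (0.81 ± 0.17 log2, SE), Rbmx2 (0.50 ± 0.11), the ubiquitin ligase gene Trim47 (0.64 ± 0.14), Bard1 (0.42 ± 0.093), which partners Brca1 in DNA repair, Pola1 (0.48 ± 0.11) and Zfp280b (0.42 ± 0.094) lay above the other mean in 12 of 12 tumours. E2F genes stood at 0.26 ± 0.081 and dendritic cell genes at -0.27 ± 0.10, both with an adjusted p = 0.221 with an estimated correlation.

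Averaged over BMS754807, 0 genes passed in limma for hydroxychloroquine (smallest adjusted p 0.0984, 1577 at an unadjusted p under 0.05). Tgfb3, a growth factor gene (0.47 ± 0.083), Timp3 (0.46 ± 0.085), the Wnt pathway receptor gene Lgr5 (0.84 ± 0.16) and the peptidase gene Cpq (0.60 ± 0.11) shared that adjusted p, followed by Stk26 (0.80 ± 0.16; 0.12) and Sbspon (1.31 ± 0.26; 0.133). Each lay above the mean of the tumours not given hydroxychloroquine in 12 of 12 tumours given it, as genes chosen by smallest p tend to do. Interferon-stimulated genes stood at -0.40 ± 0.16 and FOXO targets at 0.17 ± 0.078, both with an adjusted p = 0.727 with an estimated correlation.

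Some lists had a mean and a median of opposite sign, none of them called. Pericyte genes stood at a mean of 0.086 and a median of -0.11 with hydroxychloroquine, and FOXO targets at -0.075 and 0.12 in the interaction.

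Of 100 splits of the same tumours, the real one included, at least as many lists as in the real one were called in 50 for BMS754807 (11 lists, highest other 19), 95 for hydroxychloroquine (4, 25), 34 for the combination (13, 22), 61 for the combination against BMS754807 (9, 20) and 70 against hydroxychloroquine (9, 21). Chance could not be excluded for any of them. As 0 genes passed in each real split, all 100 of 100 splits gave as many, which excludes nothing. The highest gene counts of the other splits were 3, 17, 1, 3, 1 and 1 in the order of the report, and the 17 came from a single split of control and hydroxychloroquine tumours, which may be chance or a structure of the samples, as neither was tested.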
